A study of Homo sapiens with 8 samples.

How the data were processed

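The series measured total RNA of human glioblastoma xenograft cells on 8 one-colour expression arrays, 1 per combination of xenograft (2), CD133 fraction (CD133+ or CD133-) and laminin (with or without), after 48 hours of culture in serum-free medium. Groups, xenografts and treatment were taken from the sample titles. One description label speaks of breast cancer cell lines, against the titles, the tissue label and the growth protocol, which name glioma xenografts, and the latter were followed. The 2 replicates of a group were the 2 xenografts. Nothing in the labels says that the arrays of 1 xenograft came from separate animals or sorts, so p-values measure the spread between these arrays, part of which may be technical.

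The deposited table held 22277 probe sets, with values on the log2 scale (per the values themselves, between 2.16 and 14.49), made by the authors with RMA, per the submitters' processing notes. RMA in its usual form corrects background, quantile normalizes the arrays together and summarises the probes of a probe set, which removes differences in overall brightness between arrays. The software version and the set of arrays normalized together are not given in the sources used here. Scanner files were not used here. No batch, scan or detection call was used here. Arrays give no count-based depth, and the number of arrays sets the precision.

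Probe sets were named through the platform annotation given with the series. Of the probe sets, 62 controls were left out, 19064 had 1 gene symbol, 1043 had several and 2108 had none, and only those with 1 symbol were used. The annotation's symbols were checked through Entrez ID against a table of GRCh38.p14 gene names, which changed 0 symbols. A total of 31 probe sets of Y-linked genes and XIST were left out of all steps, which left 19033. For each of 11939 genes the probe set with the highest mean over the 8 arrays was used, and 4304 genes had more than 1. Some named genes had a probe set whose difference went the other way in at least 1 comparison in which they are named, and these were IL1R1, CD44, JAG1, PTCH1, TGFB1, TEK, ENG, COL3A1, FGFR3, ATM and SLC5A3. Folds are those of the probe set used, and other probe sets of a gene were often closer to 0, as for PDGFRA (-1.06 to -0.03) and MFNG (0.03 to 1.03) between the fractions and TOX (-1.05 to -0.14) between the xenografts. No filter on dim genes was applied in the reported values.

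Linear models were fitted to the log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided moderated tests), with Benjamini-Hochberg adjustment over the 11939 genes of a comparison and a threshold of 0.05. The CD133, laminin and xenograft comparisons came from 1 fit with these 3 factors. Laminin within each fraction, CD133 within each laminin arm and the CD133 by laminin interaction came from a fit with the 4 groups and xenograft. Interactions with xenograft were fitted by adding 1 product term to the 3 factors. Values are log2 differences with their standard errors, folds are on the unlogged scale, and n is the number of arrays per side or of matched pairs. Arrays of the same xenograft came from the same tumour, so xenograft was a block in these fits. The check of this pairing correlated the deviations of same-xenograft arrays from their group means, over 6 pairs of groups. The correlation was 0.757 between the CD133- groups, 0.409 between the CD133+ groups, and from -0.018 to 0.249 across the fractions. Arrays of 1 xenograft and fraction thus shared a deviation that 1 xenograft term does not remove. The 4 arrays of a fraction are therefore not 4 independent replicates. The pairing was taken from the titles.

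The 31 gene lists were fixed before the data were examined, as were the models, the alternatives and the rule for named genes. Lists were tested with camera at its preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the lists of a comparison. Counts of members that passed are given over all genes and adjusted over the list alone. The list tests within a fraction and for interactions were added after seeing the data. The lists overlap, for example TNC in the mesenchymal and matrix lists and TAGLN in the focal adhesion, YAP and SRF and mural lists. Named genes were, for CD133 and for laminin, the 12 with the largest rise and the 12 with the largest fall among those that passed and changed the same way in all 4 pairs, filled up to 8 by lowest unadjusted p where fewer passed. For comparisons within a fraction or arm and for interactions the rule took at most 4 per direction (filled up to 2), and for xenografts 5. It also took 2 to 4 members per list with the largest absolute difference among those that passed, and always PROM1, ITGA6, ITGB1, LAMA2, SOX2, OLIG2, NES and GFAP. From these the text gives a selection, with all of the 24 genes named by size for CD133.

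The steps were tested on simulated data for the 11939 genes, with known folds put into randomly chosen genes. For CD133 the fit recovered 70.1% of genes changed 1.5-fold and 94% of those changed 2-fold, and for laminin 65.7% and 85.1%. The laminin folds were put into both fractions alike. A rise in CD133+ cells only would add to the spread of that fit, so its percentages do not apply to such a rise. For laminin within CD133+ cells the fit recovered 83.6% of genes changed 2-fold, for the CD133 by laminin interaction 26.9%, and for the CD133 by xenograft interaction 40.3%. For xenografts 89.6% of genes changed 2-fold were recovered.

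Alternatives were quantile and cyclic loess normalization of the deposited values, a filter on dim genes, the average of all probe sets or every probe set on its own, eBayes with a mean-variance trend and robust prior, no xenograft block, each xenograft alone, a random block of arrays of 1 xenograft and fraction, pairs in place of arrays, and each array left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.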

Results

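Gene expression was measured on 8 arrays of human glioblastoma cells taken from 2 tumours grown as xenografts in an animal host, here called xenograft 1 and xenograft 2. Cells of each xenograft were separated by CD133, a surface protein encoded by PROM1 that is used to enrich glioma stem-like cells, and the CD133+ and CD133- fractions were each cultured for 48 hours in serum-free medium with or without laminin, a basement membrane protein on which such cells attach and spread. The 4 groups (CD133+ without laminin, CD133+ on laminin, CD133- without laminin and CD133- on laminin) held 2 arrays each, 1 per xenograft. The log2 expression values had medians between 6.61 and 6.68 on the 8 arrays, and 11939 genes were tested. The first principal component carried 69.3% of the variance and placed the 4 CD133+ arrays on one side and the 4 CD133- arrays on the other. The number of arrays limits the precision of every value below.

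PROM1, the gene of the sorted marker, was near the floor of the array in every sample. Its single probe set read between 2.82 and 3.43 on the log2 scale, within the lowest 4.3% of genes on each array. The difference between the fractions was 0.26 ± 0.094 (SE, n = 4 arrays per fraction), with CD133+ above CD133- in 4 of 4 matched pairs, and it did not pass the test (limma, adjusted p = 0.0733). The PROM1 transcript therefore gave no check of the sort, in either direction.

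The first comparison asked how the CD133+ and CD133- fractions differ. CD133+ cells expressed far more CCND2, a cyclin of the G1 phase, at 4.34 ± 0.35 above CD133- cells on the log2 scale (20.3-fold, SE, n = 4 arrays per fraction, adjusted p = 0.000178). ANK3, which encodes the membrane adaptor ankyrin-G, was 7.74-fold higher (2.95 ± 0.16), and the secreted phospholipase gene PLA2G3 was 5.29-fold higher (2.40 ± 0.19). In the other direction SLN, which encodes the calcium pump regulator sarcolipin, was 41.7-fold lower in CD133+ cells (-5.38 ± 0.34, adjusted p = 6.22e-05), and the protease inhibitor gene A2M was 17.4-fold lower (-4.12 ± 0.18). In all, 3947 of 11939 genes passed the test, of which 2148 were higher and 1799 lower in CD133+ cells, and 3903 of them differed in the same direction in all 4 matched pairs. Among the 429 genes that differed by over 2-fold, 91 were higher and 338 were lower in CD133+ cells.

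Further genes that were higher in CD133+ cells included the actin bundling protein gene PLS1 (4.25-fold), the chemokine gene CXCL14 (4.10-fold), the theta globin gene HBQ1 (3.68-fold), and OLIG2, a transcription factor of the oligodendrocyte lineage (3.64-fold, 1.87 ± 0.22). The neuropeptide precursor gene VGF, the synaptic vesicle gene RPH3A and the activity-regulated gene ARC were higher by 3.61, 3.61 and 3.43-fold. FUT9, whose enzyme makes the Lewis X (CD15) epitope, was 3.15-fold higher and the p38 pathway kinase gene MAP2K6 was 2.92-fold higher. Lower in CD133+ cells were LYPD1 (21.2-fold), the complement regulator CFI (19.8-fold), the doublecortin-like kinase gene DCLK1 (17.1-fold), the guidance molecule gene SEMA3C (14.6-fold) and the MHC class II genes HLA-DPA1 (13.8-fold) and HLA-DRA (13.2-fold). SEL1L3, TRDV3, C14orf132 and the transmembrane collagen gene COL13A1 were lower by 13.1, 11.7, 9.90 and 9.61-fold. Each of these genes passed the test and differed in the same direction in 4 of 4 pairs, which the rule for naming them required. The probe sets of CCND2 ranged from 0.37 to 4.34, of ANK3 from 0.22 to 2.95, of OLIG2 from 0.68 to 1.86, of FUT9 from 0.18 to 1.65, of MAP2K6 from 0.08 to 1.54, of HLA-DPA1 from -3.79 to -2.09, of SEL1L3 from -3.71 to -2.57, of DCLK1 from -4.09 to -1.42, of COL13A1 from -3.27 to -0.43 and of SEMA3C from -3.86 to -0.06, so the size of these differences depended on the probe set. In CD133+ cells SEMA3C (3.23 to 3.58) and TRDV3 (3.06 to 3.53) read near the floor, in the lowest 5.7% and 5.2% of genes. There CFI (4.20 to 4.75), HLA-DRA (4.01 to 4.80) and HLA-DPA1 (4.04 to 4.82) read in the lowest 16.3%, 16.5% and 16.9%. ANK3 in CD133- cells (3.90 to 4.24) read in the lowest 11%. The folds of these 6 genes and their order are therefore not exact.

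**Figure D1:**
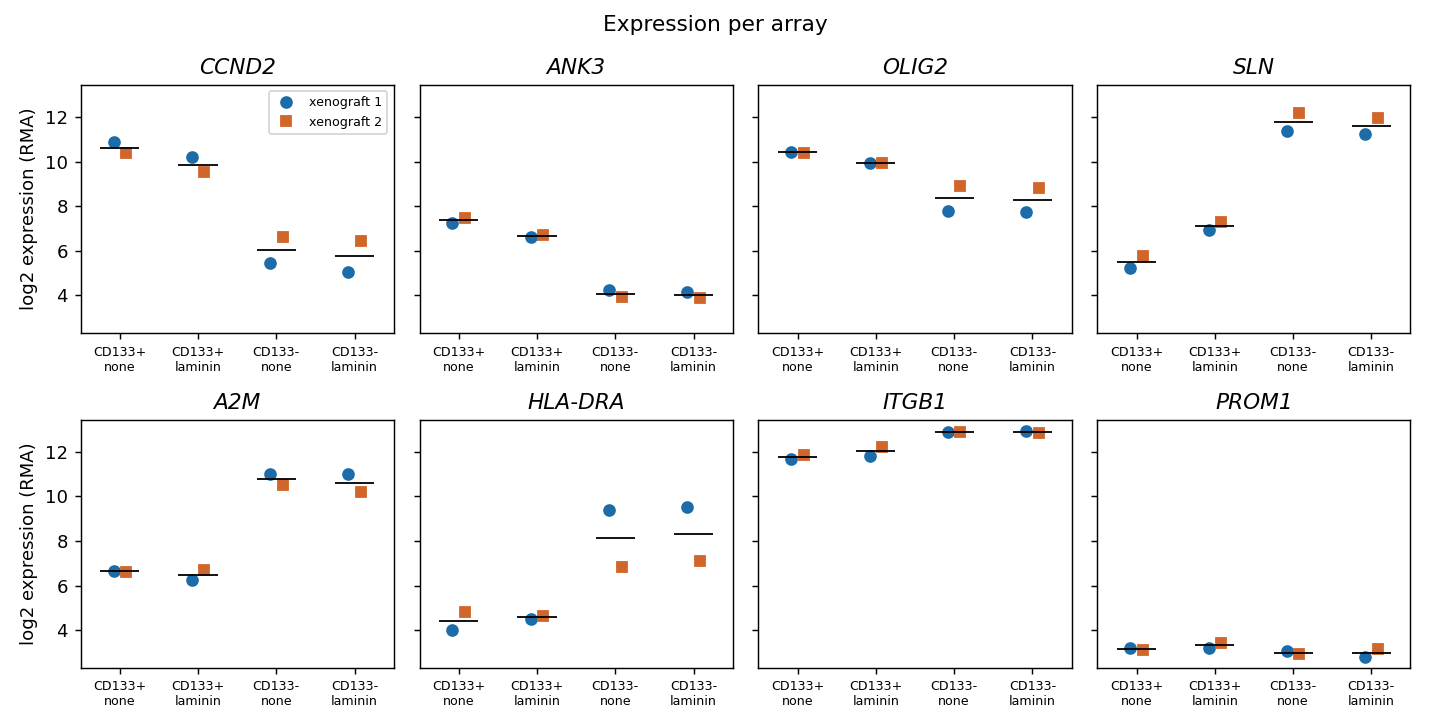
Log2 expression of 8 genes on each array, by CD133 fraction and laminin, with circles for xenograft 1, squares for xenograft 2 and a line at the mean of the 2 arrays of a group. CCND2, ANK3 and OLIG2 were higher and SLN, A2M, HLA-DRA and ITGB1 lower in CD133+ cells, while PROM1 lay between 2.82 and 3.43 on all arrays.

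Cell cycle genes were higher in CD133+ cells as a group. All 25 measured genes of the G2 and M phase list passed the test and were higher, with a median log2 difference of 1.01, among them CDC20 (2.70-fold), the mitotic kinase genes AURKB (2.49-fold) and AURKA (2.42-fold), and UBE2C (2.30-fold). Of 23 S phase genes, 20 were higher and 0 lower (median 0.57), with GINS2 at 2.15-fold and the replicative helicase gene MCM7 at 1.68-fold. Of 14 cholesterol synthesis genes, 9 were higher and 0 lower (median 0.51), including SQLE (1.59-fold) and HMGCS1 (1.51-fold). The adjusted p of the competitive list test (camera) was 1.84e-11, 3.86e-07 and 0.000303 for these 3 lists. With an estimated correlation between genes, none of the 31 lists passed in this comparison, and the adjusted p was 0.445 with an estimated correlation for each of these 3 lists. The counts adjusted over the list alone were 25, 20 and 11.

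Genes of the mesenchymal glioblastoma state, of matrix and adhesion, and of antigen presentation were lower in CD133+ cells. In the mesenchymal list 17 of 25 genes were lower and 0 higher (median -0.94, adjusted p = 3.06e-09), with the matrix glycoprotein gene TNC at 5.26-fold lower, IL1R1 at 4.66-fold, the hyaluronan receptor gene CD44 at 3.12-fold and TGFBI at 2.75-fold. Among 30 other extracellular matrix genes, 20 were lower and 1 higher (median -0.87, adjusted p = 9.51e-08), including THBS1 (6.17-fold, with its 5 probe sets from -2.63 to -0.02), COL6A2 (4.03-fold) and COL5A2 (3.64-fold). Of 16 MHC class I and II genes, 12 were lower and 0 higher (median -1.16, adjusted p = 3.86e-07), including HLA-DMA (4.96-fold) and the class I gene HLA-B (3.80-fold). With an estimated correlation the adjusted p was 0.445 for each of these 3 lists. Adjusted over the list alone, 18, 23 and 12 genes passed. In CD133+ cells IL1R1 (3.88 to 4.58) and HLA-DMA (3.86 to 4.40) read in the lowest 14.8% and 13% of genes. THBS1 read 3.67 and 3.10 in CD133+ cells without laminin, in the lowest 6.9%. The folds of IL1R1, HLA-DMA and THBS1 are therefore not exact.

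Receptors for laminin were also lower in CD133+ cells. Of 21 laminin receptor and integrin genes, 12 were lower and 0 higher (median -0.40, adjusted p = 7.02e-05), with ITGA3 4.26-fold lower, the syndecan gene SDC2 3.32-fold, ITGA7 2.44-fold and ITGAV 2.36-fold lower. ITGB1, the beta chain shared by most laminin-binding integrins, was 1.98-fold lower (-0.98 ± 0.099, adjusted p = 0.000394, with its 5 probe sets from -0.98 to -0.03), whereas ITGA6 (0.26 ± 0.10, adjusted p = 0.0941) and the laminin chain gene LAMA2 (-0.15 ± 0.069, adjusted p = 0.133) did not pass. Of 10 laminin chain genes, 4 were lower, led by LAMB3 (2.71-fold), and 1 was higher. Of 23 focal adhesion genes, 12 were lower and 1 higher, with CAV1 4.73-fold lower and TAGLN 2.28-fold lower. Of 18 YAP and SRF target genes, 8 were lower and 1 higher, with NT5E 6.17-fold lower. The adjusted p was 0.0479 for laminin chains, 0.000123 for focal adhesion and 0.00456 for YAP and SRF targets. For each of these 4 lists the adjusted p was 0.445 with an estimated correlation. Counts adjusted over the list alone were 14 integrin, 6 laminin chain, 15 focal adhesion and 10 YAP and SRF target genes.

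Of 24 hypoxia genes, 12 were lower and 3 higher (adjusted p = 0.00569), including the adrenomedullin gene ADM at 3.61-fold and VEGFA at 2.14-fold lower. Of 18 BMP and TGF-beta targets, 8 were lower and 3 higher (adjusted p = 0.0315), with SMAD7 4.72-fold and TGFB1 2.44-fold lower. Of 21 interferon-stimulated genes, 5 were lower and 1 higher (adjusted p = 0.0333), with IRF9 2.40-fold lower. Of 12 p53 targets, 4 were lower and 0 higher (adjusted p = 0.048), including CDKN1A at 1.61-fold. Of 10 heat shock genes, 6 were higher, including HSPA4L at 1.86-fold, and CRYAB was lower at 1.95-fold (adjusted p = 0.0378). Of 17 ribosomal protein genes, 6 were higher and 0 lower, by 1.26-fold for RPL35 (adjusted p = 0.0208). With an estimated correlation the adjusted p was 0.554 for the interferon list and 0.445 for the other lists of this paragraph. The list calls for laminin chains, heat shock, p53 targets and ribosomal proteins were lost after quantile or cyclic loess normalization, and those for interferon and BMP and TGF-beta targets after cyclic loess. The BMP and TGF-beta call was also lost with only genes above the median mean (adjusted p = 0.919), and those for laminin chains, interferon, heat shock and p53 targets without single arrays (highest adjusted p 0.0975, 0.0647, 0.0546 and 0.13). Adjusted over the list alone, 15 hypoxia, 13 BMP and TGF-beta, 6 interferon, 4 p53, 10 heat shock and 6 ribosomal genes passed.

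**Figure D2:**
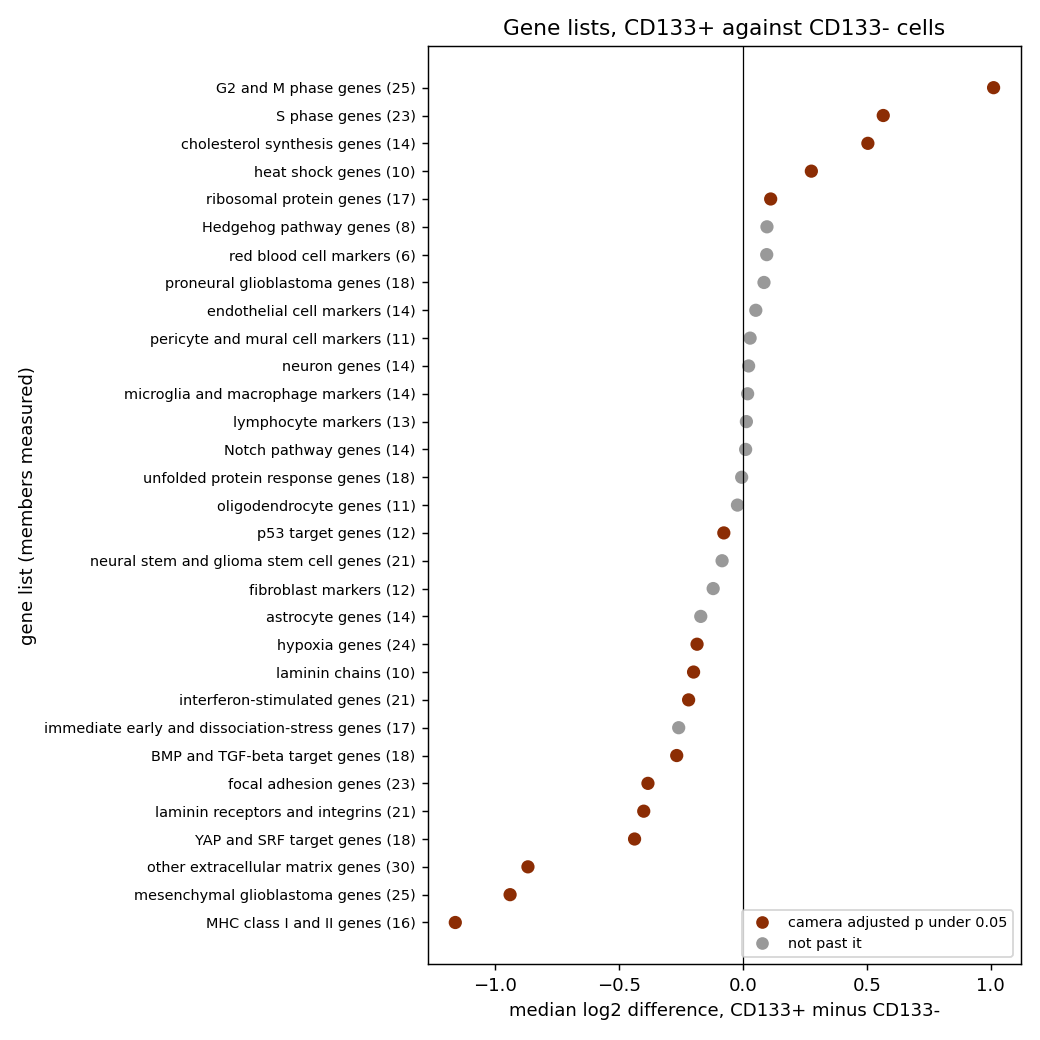
Median log2 difference between CD133+ and CD133- cells (horizontal axis) for each of 31 gene lists (vertical axis, with the number of measured members), coloured by whether the list passed camera with its preset correlation. The G2 and M phase list lay highest at 1.01 and the MHC list lowest at -1.16.

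Stem cell genes showed no common direction. Of 21 neural and glioma stem cell genes, 3 were higher and 4 lower in CD133+ cells (adjusted p = 0.557), with OLIG2 and MYC (1.38-fold) higher and HEY1 (1.77-fold), POU3F2 (1.64-fold) and the intermediate filament gene NES (-0.36 ± 0.089, adjusted p = 0.0166) lower. SOX2 (-0.12 ± 0.069, adjusted p = 0.251) and GFAP (-0.16 ± 0.13, adjusted p = 0.406) did not pass. The proneural list had 5 of 18 genes higher and 3 lower, with CKB (1.91-fold) higher and PDGFRA (2.09-fold) lower (adjusted p = 0.586). The Notch list had 2 of 14 genes higher and 4 lower, with JAG1 2.03-fold lower and MFNG 2.05-fold higher (adjusted p = 0.648). Of 8 Hedgehog genes, PTCH1 (2.02-fold) and GLI1 (1.48-fold) were higher (adjusted p = 0.296). The unfolded protein response list (7 of 18 higher and 3 lower, with ASNS 2.06-fold higher, adjusted p = 0.796) and the immediate early list (2 of 17 higher and 8 lower, with EGR3 2.51-fold lower, adjusted p = 0.0599) did not pass. The genes that passed when adjusted over the list alone were 7 stem cell, 8 proneural, 6 Notch, 2 Hedgehog, 11 unfolded protein response and 10 immediate early genes.

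Markers of other cell types did not separate the fractions as lists. Cells of the animal host would be read by these probe sets for human genes only as far as their RNA cross-hybridises. The marker lists therefore do not exclude host cells in either fraction. The adjusted p was 0.0846 for 14 astrocyte genes (1 higher, 4 lower, CLU 2.01-fold lower), 0.954 for 14 neuron genes (4 higher, 4 lower, MAP2 2.46-fold higher and SNAP25 2.22-fold lower) and 0.745 for 11 oligodendrocyte genes (0 passed). For 14 endothelial markers it was 0.811, with 1 higher and 3 lower, among them the VEGF receptor gene KDR at 8.23-fold lower. For 11 mural cell markers it was 0.954 (2 higher, 2 lower, TAGLN lower and MCAM higher) and for 12 fibroblast markers 0.094 (3 lower, COL3A1 by 3.44-fold). It was 0.954 for 14 microglia and macrophage markers (1 passed, C1QB at 1.22-fold higher), 0.843 for 6 red blood cell markers and 0.789 for 13 lymphocyte markers, with 0 members past the threshold in the last 2 lists. Adjusted over the list alone, 5 astrocyte, 8 neuron, 4 endothelial, 5 mural and 3 fibroblast genes passed, and 0 of the oligodendrocyte, microglia, red blood cell and lymphocyte genes.

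The split of calls in this comparison depended on scaling, since after cyclic loess normalization 1743 genes were higher and 2214 lower in CD133+ cells. With xenograft 2 alone 1820 genes passed, and with the laminin arms averaged first, so that the 2 tumours gave 2 pairs as a replicate block, 1786 passed.

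The second comparison asked what growth on laminin changed. Over both fractions together, 0 of 11939 genes passed the test (limma, lowest adjusted p = 0.801), and 734 had an unadjusted p under 0.05. The genes with the lowest unadjusted p and the same sign in all 4 pairs had small differences, such as the lamin A gene LMNA (0.43 ± 0.085), the adhesion molecule gene L1CAM (0.55 ± 0.11), S100A4 (0.41 ± 0.088) and NDRG1 (0.68 ± 0.14) with values above 0, and HMGN5 (-0.56 ± 0.11) and the proteoglycan genes CSPG5 (-0.37 ± 0.080) and NCAN (-0.42 ± 0.11) with values below 0. The laminin differences of ITGA6 (0.26 ± 0.10), ITGB1 (0.13 ± 0.099), SOX2 (0.02 ± 0.069), NES (0.04 ± 0.089) and OLIG2 (-0.29 ± 0.22) did not pass either.

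As lists, 9 of 31 passed camera for laminin over both fractions. Higher on laminin were the mesenchymal (median 0.21, adjusted p = 6.53e-11), focal adhesion (0.17, 8.8e-06), hypoxia (0.10, 8.8e-06), YAP and SRF target (0.18, 0.000126), integrin (0.15, 0.000234), immediate early (0.12, 0.0163) and lymphocyte marker lists (0.09, 0.0235), the last lost under quantile normalization. The S phase (-0.11, 0.000116) and proneural (-0.11, 0.0142) lists were lower. Single arrays ended the calls for the S phase, proneural, immediate early and lymphocyte lists (highest adjusted p 0.0851, 0.126, 0.162 and 0.232). With an estimated correlation 0 lists passed, and the adjusted p lay between 0.633 and 0.696 with an estimated correlation for these 9 lists. No member of any of the 9 lists passed over all genes. Adjusted over the list alone, 1 proneural and 1 hypoxia gene passed, and 0 in the other 7 lists.

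Within CD133+ cells 42 genes passed for laminin, all of them higher on laminin and 29 by over 2-fold. EMP1 was 7.10-fold higher on laminin (2.83 ± 0.18, SE, n = 2 pairs, adjusted p = 0.00457), the caveolin gene CAV1 6.03-fold (2.59 ± 0.16, adjusted p = 0.00457) and RGS4, a regulator of G protein signalling, 5.75-fold (2.52 ± 0.14, adjusted p = 0.00411). THBS1, which encodes the matrix protein thrombospondin 1, rose too (2.95 ± 0.26, adjusted p = 0.013), but from 3.67 and 3.10 without laminin, near the floor, so the size of its rise is not exact. The laminin-binding integrin genes ITGA3 (3.68-fold) and ITGA7 (2.25-fold) and the syndecan gene SDC4 (1.73-fold) rose, as did CD44 (3.12-fold), ANXA1 (2.98-fold), ANXA2 (2.08-fold) and LGALS3 (2.03-fold) of the mesenchymal list. The ecto-nucleotidase gene NT5E (4.90-fold), EGR1 (2.46-fold), ADM (2.43-fold), FGFR3 (2.16-fold), IER3 (1.91-fold), the Notch ligand gene JAG1 (1.85-fold) and the glucose transporter gene SLC2A3 (1.83-fold) rose too. The probe sets of THBS1 ranged from 0.03 to 2.95, those of EMP1 from 1.41 to 2.90, of RGS4 from 1.01 to 2.52, of CD44 from 0.17 to 1.66, of JAG1 from 0.06 to 1.07 and of FGFR3 from -0.05 to 1.11. The values below 0 with the lowest unadjusted p did not pass (ADA -0.75 ± 0.099, adjusted p = 0.0521, and DUSP10 -0.90 ± 0.13, adjusted p = 0.0627), nor did ID1 (1.27 ± 0.23, adjusted p = 0.133) or L1CAM (0.78 ± 0.11, adjusted p = 0.07).

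Tested as lists within CD133+ cells, a comparison added after seeing the data, 10 of 31 passed camera. The mesenchymal list had 4 of 25 genes higher (14 adjusted over the list alone, median 0.39, adjusted p = 4.29e-18), the integrin list 3 of 21 (5 adjusted over the list alone, adjusted p = 9.94e-07) and the YAP and SRF list 2 of 18 (9 adjusted over the list alone, adjusted p = 5.74e-09). For each of these 3 lists the adjusted p was 0.135 with an estimated correlation, and 0 of the 31 lists passed that way. Also higher were the focal adhesion (median 0.28, adjusted p = 1.28e-07, adjusted p = 0.527 with an estimated correlation), hypoxia (0.14, 1.98e-07, 0.432), immediate early (0.20, 0.000128, 0.383), extracellular matrix (0.01, 0.00916, 0.604) and unfolded protein response lists (0.10, 0.0362, 0.527), with 1 of 23, 2 of 24, 2 of 17, 1 of 30 and 0 of 18 genes past the threshold. The proneural list (median -0.23, adjusted p = 0.000983, adjusted p = 0.383 with an estimated correlation) and the S phase list (-0.11, 0.0121, 0.856) were lower, with 0 genes past the threshold in each. The S phase call was lost with only genes above the median mean (0.0995), and changed direction without the untreated CD133+ array of xenograft 1 (0.867) or the CD133+ laminin array of xenograft 2 (0.98). Without the latter the matrix call was also lost (0.506), as was the unfolded protein response call without the untreated CD133+ array of xenograft 2 (0.513). When adjusted over the list alone, these 7 lists had 6, 8, 5, 8, 0, 2 and 0 genes that passed. In the 42-gene set the count was 168 (149 higher and 19 lower) when each xenograft and fraction was its own replicate block, and leaving out 1 array lowered it. It was 0 and 1 without the CD133+ laminin array of xenografts 1 and 2, 6 and 6 without the untreated CD133+ array, 26 and 26 without the untreated CD133- array, and 14 and 14 without the CD133- laminin array.

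Within CD133- cells 0 genes passed for laminin by limma, and 195 had an unadjusted p under 0.05. The genes with the lowest unadjusted p in each direction, ERC2-IT1 (0.68 ± 0.12) and SLC12A8 (-0.40 ± 0.092), had adjusted p = 1. As lists, 1 of 31 passed camera in CD133- cells, the S phase list with a median of -0.11 (adjusted p = 0.00454, adjusted p = 0.987 with an estimated correlation) and 0 of 23 genes past the threshold, over all genes or over the list alone. It changed direction without the CD133- laminin array of xenograft 1 (adjusted p = 0.826) or the untreated CD133- array of xenograft 2 (0.546). The 42 genes raised in CD133+ cells had a median difference of 1.15 there and of 0.07 in CD133- cells, where none of them passed and the values ran from -0.19 to 0.35. These genes were chosen for their rise in CD133+ cells, which favours a larger median there, so only the interaction tests whether the fractions differ. The difference between the fractions in the response to laminin, tested as an interaction, passed for 9 genes, all with the larger rise in CD133+ cells. They included EMP1 (2.71 ± 0.25, adjusted p = 0.0446), CAV1 (2.50 ± 0.22, adjusted p = 0.0446), RGS4 (2.42 ± 0.20, adjusted p = 0.0446), ITGA3 (2.07 ± 0.15, adjusted p = 0.0344), CD44 (1.63 ± 0.12, adjusted p = 0.0344) and ITGA7 (1.28 ± 0.13, adjusted p = 0.0457). With a replicate block for each xenograft and fraction 23 genes passed, and with any 1 array left out 0 passed.

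**Figure D3:**
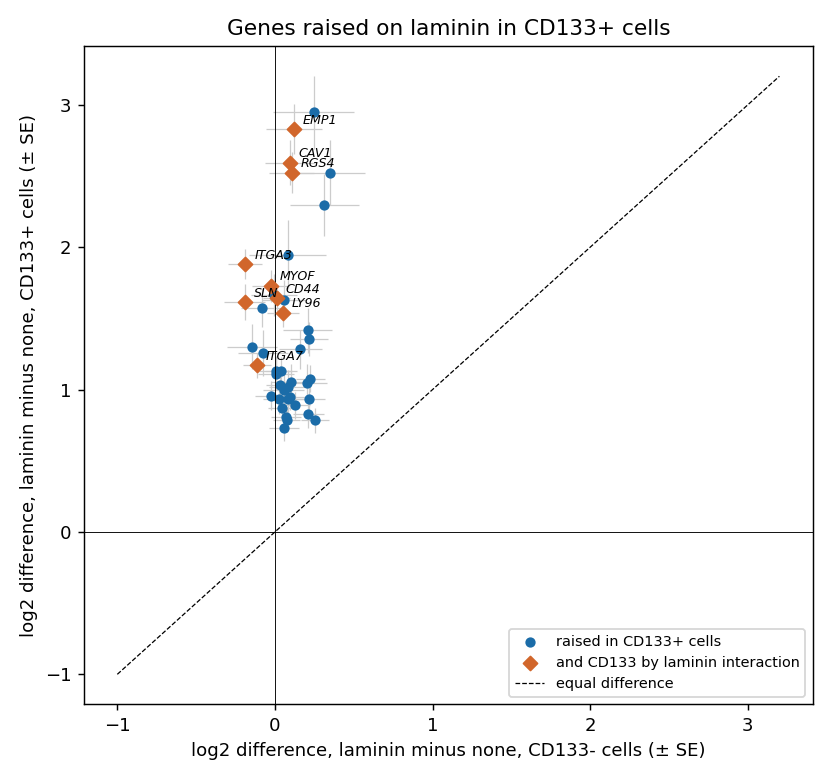
Log2 difference between laminin and no laminin in CD133- cells (horizontal axis) and CD133+ cells (vertical axis), each with its SE, for the 42 genes raised in CD133+ cells, with diamonds for genes with a called interaction. The genes were chosen for their rise in CD133+ cells, which favours a place above the dashed line of equal difference, and all 42 lay above it, with a median of 1.15 in CD133+ and 0.07 in CD133- cells.

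The genes raised by laminin in CD133+ cells were genes with lower expression in CD133+ than in CD133- cells. Of the 42, 41 were called lower in CD133+ cells without laminin, against 4.01 expected from independent lists, and 31 were called lower on laminin, against 3.06. RGS4 in CD133+ cells averaged 5.59 without laminin and 8.11 on laminin, beside 7.94 in CD133- cells without laminin. CD44 averaged 9.57 and 11.21 in CD133+ cells and 12.03 in CD133- cells, and CAV1 6.20 and 8.80 beside 9.69. Both comparisons used the same untreated CD133+ arrays, and in 100 simulations without any effect a median of 88.1% and at most 100% of the 42 genes raised most were higher in CD133- cells. The observed 97.6% lay within that range, so the shared direction may come in part from the shared arrays. The simulations counted direction only, so they do not give the number of genes that would be called lower. With the laminin difference from 1 xenograft and the CD133 difference from the other, which share no array, 93% and 97% of the 100 genes raised most were higher in CD133- cells.

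The CD133 difference was present in each laminin arm. Without laminin 2354 genes passed (1214 higher and 1140 lower in CD133+ cells), led by CCND2 (24.2-fold higher), ANK3 (9.75-fold), CXCL14 (5.97-fold) and SLN (77.9-fold lower). After cyclic loess normalization the split was 873 higher and 1413 lower. On laminin 1597 genes passed (728 higher and 869 lower), led by CCND2 (17.1-fold higher), ANK3 (6.14-fold), PLA2G3 (6.03-fold), VGF (5.29-fold) and SLN (22.3-fold lower). ANK3 read between 3.90 and 4.24 in CD133- cells, in the lowest 11% of genes, so its folds in both arms are not exact. The split on laminin was 601 higher and 1037 lower after cyclic loess normalization, 1165 and 939 with only genes above the median mean, and 1105 and 1083 with a mean-variance trend and robust prior. The arms shared 1356 called genes, and 1354 of these had the same sign in both. Without xenograft as a replicate block, 1428 and 757 genes passed. The count without laminin fell to 607 and 643 when the untreated CD133+ or CD133- array of xenograft 1 was left out, with 134 and 150 higher and 473 and 493 lower. On laminin it fell to 110 and 103 without the CD133+ or CD133- array of xenograft 1 (13 and 15 higher, 97 and 88 lower), and to 429 and 312 without those of xenograft 2 (102 and 57 higher, 327 and 255 lower).

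The CD133 difference was not of the same size in both xenografts. IGFBP7, which encodes a secreted IGF-binding protein, was 10.26 in CD133- cells of xenograft 1 and 7.29 in those of xenograft 2, while CD133+ cells had 6.02 and 6.24, an interaction of 3.19 ± 0.14 on the log2 scale (adjusted p = 0.000698). HLA-DRA was 9.46 and 6.97 in CD133- cells of the 2 xenografts (interaction 2.93 ± 0.22, adjusted p = 0.00473), with like interactions for HLA-DPA1 (2.78 ± 0.26) and TMEM45A (2.40 ± 0.30). GNL3L (-2.80 ± 0.38), GTF2H3 (-2.29 ± 0.20), the DNA damage kinase gene ATM (-2.21 ± 0.14) and GINS4 (-2.19 ± 0.18) had the largest called interactions below 0, although the probe sets of IGFBP7 ranged from 0.35 to 3.19, those of GNL3L from -2.80 to -0.18 and those of ATM from -2.21 to 0.02. In all 446 genes had a called interaction, 192 above and 254 below 0, and for 399 of them the CD133- level differed more between the xenografts than the CD133+ level. Each xenograft and fraction gave 1 array without laminin and 1 on laminin. The SE and p-values of this interaction therefore measure the spread between those arrays, not between separate sorts or preparations. Leaving out 1 array gave counts of 139 and 28 for the untreated CD133+ array of xenografts 1 and 2, 23 and 22 for the untreated CD133- array, 124 and 90 for the CD133- laminin array, and 41 for the CD133+ laminin array of xenograft 2.

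Cell cycle genes made up a clear part of this interaction in a test of the lists added after seeing the data. For G2 and M phase genes 21 of 25 had an interaction below 0 (25 adjusted over the list alone, median -0.77, adjusted p = 1.51e-25, adjusted p = 0.132 with an estimated correlation), so the CD133+ excess was larger in xenograft 1. TOP2A, for example, was 8.64 and 9.78 in CD133- cells of xenografts 1 and 2 and 10 and 10.14 in CD133+ cells. S phase genes (8 of 23 below 0, median -0.44, adjusted p = 6.99e-13, adjusted p = 0.112 with an estimated correlation) and cholesterol synthesis genes (2 of 14 below 0, adjusted p = 8.09e-05) went the same way. MHC genes had 7 of 16 interactions above 0 (median 0.56, adjusted p = 9.27e-08), with smaller shifts for extracellular matrix (5 of 30, adjusted p = 0.00512), focal adhesion (3 of 23, adjusted p = 0.00114) and interferon-stimulated genes (3 of 21, adjusted p = 0.00172). With an estimated correlation the adjusted p was 0.182 for the cholesterol, MHC and interferon lists, 0.35 for the matrix list and 0.649 for the focal adhesion list. The matrix call was lost without the CD133+ laminin array of xenograft 2 (0.0513) and the focal adhesion call without the untreated CD133+ array of xenograft 1 (0.108). Adjusted over the list alone, 16 S phase, 9 cholesterol, 10 MHC, 9 matrix, 7 focal adhesion and 6 interferon genes passed.

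Between the xenografts, with fraction and laminin held fixed, 33 genes passed, 2 higher and 31 lower in xenograft 2. Agreement in 4 of 4 pairs was a condition for naming the genes that follow. IRX4 (1.42-fold) and the inositol transporter gene SLC5A3 (1.39-fold) were higher in xenograft 2, in 4 of 4 pairs. DNAJC15 (3.64-fold, -1.86 ± 0.089, adjusted p = 0.000471), the neuritin gene NRN1 (2.71-fold), RNF128 (2.60-fold), the transcription factor gene TOX (2.07-fold) and the adhesion gene NECTIN3 (2.05-fold) were lower, in 4 of 4 pairs, with TOX near the floor in xenograft 2 (3.24 to 3.73). Tested by fraction, a step added after seeing the data, 6 genes differed between the xenografts in CD133+ cells and 1617 in CD133- cells. The median absolute log2 difference was 0.117 and 0.148, and 2047 and 3501 genes had an unadjusted p under 0.05. These p-values by fraction measure the spread between the laminin arms of a xenograft and fraction, not between separate sorts or preparations. The count of 33 rose to 73 without the untreated CD133+ array of xenograft 1 and fell to 3 and 5 without the CD133+ laminin array of xenografts 1 and 2, to 4 and 3 without the untreated CD133- array, to 2 and 2 without the CD133- laminin array, and to 5 without the untreated CD133+ array of xenograft 2. No difference in the laminin response between the xenografts was called by limma (0 of 11939 genes, with 126 or 1.1% at an unadjusted p under 0.05). That fit had no CD133 by xenograft or CD133 by laminin term, so those differences stayed in its spread. Recovery of known changes was not simulated for it, so the count of 0 does not show that the responses were alike. The genes with the lowest unadjusted p in each direction, GRIA1 (-0.76 ± 0.18) and ATF7 (0.58 ± 0.14), had adjusted p = 1.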

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

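The tests on the CD133 difference between xenografts and on chromosome medians were chosen after the result was seen, and those on shared arrays and on mixed cells in CD133+ cultures were chosen before they were run.

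Laminin had a different effect in the CD133 fractions for 9 genes, which drew attention because the difference between groups was itself called. The genes named among them, each with its log2 interaction, SE and adjusted p, were EMP1 (2.71 ± 0.25, 0.0446), CAV1 (2.50 ± 0.22, 0.0446), RGS4 (2.42 ± 0.20, 0.0446), ITGA3 (2.07 ± 0.15, 0.0344), SLN (1.81 ± 0.18, 0.0468), CD44 (1.63 ± 0.12, 0.0344) and ITGA7 (1.28 ± 0.13, 0.0457). SLN in CD133+ cells averaged 5.51 without laminin and 7.12 on laminin.

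The CD133 difference was not the same in the 2 xenografts for 446 genes, and the values below are the log2 interaction (xenograft 2 minus xenograft 1), SE and adjusted p. The SE and adjusted p measure the spread between the laminin arms of a xenograft and fraction, not between separate sorts. Called values below 0 were found for 21 of 25 G2 and M phase genes and 8 of 23 S phase genes. Named genes with values below 0 included CCND2 (-1.86 ± 0.23, 0.0128), CCNA2 (-1.09 ± 0.19, 0.0319), CCNE2 (-1.06 ± 0.13, 0.0124), CDK1 (-0.96 ± 0.11, 0.0124), CDC20 (-0.90 ± 0.11, 0.0144), CDC6 (-0.74 ± 0.12, 0.0263), TOP2A (-1.01 ± 0.12, 0.0126), HMMR (-0.98 ± 0.11, 0.0124), AURKB (-0.84 ± 0.13, 0.0258), AURKA (-0.77 ± 0.13, 0.0277), TTK (-0.78 ± 0.11, 0.0192), BUB1B (-0.77 ± 0.11, 0.0202), UBE2C (-0.72 ± 0.13, 0.0348), RRM2 (-0.69 ± 0.12, 0.033), RFC4 (-0.72 ± 0.11, 0.0249), GINS1 (-0.67 ± 0.11, 0.0286), GINS2 (-0.67 ± 0.12, 0.0362), GINS4 (-2.19 ± 0.18, 0.00473), ATM (-2.21 ± 0.14, 0.00473), GTF2H3 (-2.29 ± 0.20, 0.00506) and GNL3L (-2.80 ± 0.38, 0.0169). CDK1, the kinase that drives entry into mitosis, averaged 9.95 and 11.03 in CD133- cells of xenografts 1 and 2, and 11.29 and 11.41 in CD133+ cells.

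Called values above 0 were found for 7 of 16 MHC genes and 3 of 21 interferon-stimulated genes, among them HLA-DRA (2.93 ± 0.22, 0.00473), HLA-DPA1 (2.78 ± 0.26, 0.00624), HLA-DMA (1.69 ± 0.21, 0.013), HLA-DPB1 (1.22 ± 0.13, 0.0102), HLA-B (0.88 ± 0.13, 0.0203), IFIT1 (1.22 ± 0.21, 0.033), IFI44 (1.02 ± 0.20, 0.0432) and IFIT2 (0.73 ± 0.15, 0.0498). Called values above 0 were also found for 5 of 30 matrix, 3 of 23 focal adhesion and single other genes, with MMP2 (1.42 ± 0.15, 0.00896), COL3A1 (1.40 ± 0.27, 0.0427), LTBP2 (1.33 ± 0.11, 0.00473), COL1A2 (1.29 ± 0.23, 0.0348), COL5A1 (1.14 ± 0.18, 0.0258), ACTA2 (1.15 ± 0.18, 0.0239), TGFBR2 (0.91 ± 0.15, 0.0283), LAMB3 (0.87 ± 0.14, 0.0273), TLN2 (0.84 ± 0.13, 0.0203) and ILK (0.58 ± 0.12, 0.0452), whereas the proteoglycan genes DCN and LUM and the SMAD repressor gene SKIL had values below 0, with DCN (-1.49 ± 0.15, 0.00815), LUM (-1.47 ± 0.28, 0.0399) and SKIL (-1.20 ± 0.24, 0.0452).

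Values above 0 were also found for IGFBP7 (3.19 ± 0.14, 0.000698), TMEM45A (2.40 ± 0.30, 0.013), SEMA3C (2.36 ± 0.25, 0.00972), TRDV3 (1.40 ± 0.14, 0.00893), SEL1L3 (1.34 ± 0.16, 0.0124), CRYAB (1.17 ± 0.15, 0.0146), FOSL2 (0.96 ± 0.13, 0.017) and HEY1 (0.76 ± 0.12, 0.0249). Other probe sets gave values nearer 0 for several of these genes, down to 0.04 for COL3A1 and COL5A1, 0.15 for COL1A2, 0.24 for IFI44, 0.08 for FOSL2 and 0.35 for IGFBP7. Averages per xenograft and fraction were low throughout for IFI44 (3.66 to 4.51), IFIT1 (3.89 to 4.9) and LUM (3.06 to 4.63). The sizes of the interactions of IFI44, IFIT1 and LUM are therefore not exact. Values below 0 were found for the glial lineage genes OLIG2 (-1.13 ± 0.18, 0.0266) and CSPG4 (-0.70 ± 0.13, 0.039), for the synaptic gene ARC (-0.97 ± 0.14, 0.0197) and the fucosyltransferase gene FUT9 (-1.79 ± 0.25, 0.017), for the sterol pathway genes DHCR7 (-0.93 ± 0.12, 0.0157) and PMVK (-0.90 ± 0.13, 0.0178), and for BAX (-0.93 ± 0.14, 0.023), HSPA4L (-0.90 ± 0.17, 0.0401) and PHGDH (-0.64 ± 0.12, 0.0382).

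For the genes raised by laminin in CD133+ cells, shared untreated CD133+ arrays could be set aside as the only cause. When the laminin difference came from 1 xenograft and the CD133 difference from the other, 93% of the 100 genes raised most were higher in CD133- cells, against at most 59% in 1000 draws of genes matched on mean expression. A single share of CD133- cells among the CD133+ cells on laminin was also set aside, since the share each gene would need ran from 0.9% at the 10th percentile to 37.9% at the 90th over 65 genes and was alike in the 2 xenografts across genes (Spearman rho = 0.81, genes not being independent). RGS4 would need a share of 116.3% and A2M -0.5%. A change of particular genes in CD133+ cells, or cells of another kind in these cultures, remains possible.

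For the CD133 difference between xenografts, CD133+ cells in the CD133- fraction of xenograft 2 were examined as the whole cause. Mixed cells bring the CD133- level toward the CD133+ level and cannot take it past that level. For 58 of the 446 genes the CD133 difference was called in opposite directions in the 2 xenografts, against 22.3 false calls allowed by the threshold. GINS4, for example, was higher in CD133+ cells of xenograft 1 (1.71, adjusted p = 0.000119) and lower in those of xenograft 2 (-0.49, adjusted p = 0.0329). The 22.3 is the allowance for interaction calls, not the number of opposite calls expected with mixing. The 446 genes were also chosen for a large interaction in the same arrays, which favours opposite signs. The count of 58 therefore does not decide the question. For the 256 genes in between, the share of mixed cells each would need was spread over 54.2 points between the 10th and 90th percentiles. That value takes the CD133- cells of the 2 xenografts to be alike apart from mixing, as mixing as the whole cause would require. In 1000 simulations of 1 share with noise, the spread had a median of 21 points and a maximum of 24.9. For these 256 genes the spread thus argues against 1 share of mixed cells as the whole cause. The simulated noise came from arrays of the same xenograft and fraction, so it leaves out variation between sorts. Mixing as a part of the cause remains possible.

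The CD133+ arrays of the 2 xenografts were alike, with a correlation across genes of 0.9955 without laminin, genes not being independent. The test took 1 source of cells to give median differences by chromosome as small as with genes assigned to chromosomes at random. Their SD was 0.02, against a random median of 0.013 and maximum of 0.022, with 8 of 1000 random draws as large (share 0.009). In CD133- cells it was 0.036, with 0 of 1000 draws as large. The draws separate neighbouring genes that may change together, so an SD above most draws could also arise with 1 source. Between the CD133+ arrays of the xenografts 6 genes were called by limma. Of these, DNAJC15 (-1.83, adjusted p = 0.016) and RNF128 (-1.41, adjusted p = 0.0262) shifted as they did in CD133- cells (-1.90 and -1.34). NAV3 (-1.69) and SPARCL1 (1.06) shifted less in CD133- cells (-0.58 and 0.55). BAX (-1.08) and PMVK (-0.92) hardly shifted there (-0.14 and -0.01). The shifts of DNAJC15 and RNF128 in both fractions go against 1 source, but they are only 2 genes. The SD stayed below the 0.1 set as the mark of separate sources, and separate handling of 1 source, which was not tested, would also shift single genes, so the question stays open.

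A random division of the arrays was examined over the 35 splits of 8 arrays into 4 and 4. For CD133, 1 split (the real one) gave 3947 genes and the highest other gave 1. The other splits were fitted without CD133 as a factor, so the CD133 difference stayed in their spread and lowered their counts. The real split thus ranked first, but the size of the gap does not measure chance. For CD133 gene lists 1 split (the real one) gave 16, and the highest other gave 14. Splits that followed no labelled factor gave up to 14 lists, so the list count does not exclude chance. For laminin the real split gave 0 genes by limma (734 with an unadjusted p under 0.05), so all 35 splits had to give as many and the count says nothing about chance. The highest other gave 3967, which was the split by CD133 and points to sample structure. For laminin gene lists 12 splits gave at least the real 9, with 15 the highest other, so chance cannot be excluded. For the xenografts 2 splits gave at least the real 33, with 3228 the highest other, so chance cannot be excluded by this count. The highest other was again the split by CD133, which points to sample structure, and the remaining splits gave at most 5.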

How the results depend on the processing

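The count of 3947 genes for CD133 was 2891 to 3540 when 1 array was left out, 3336 with xenograft 1 alone, and 4028 without both CD133- arrays of xenograft 2, of which 3194 were among the 3947. With xenograft 2 alone it was 1820, and with the laminin arms averaged first it was 1786. The cause was not tested, and xenograft 1 alone has as many arrays as xenograft 2 alone. Of 120 named calls, 109 held with every array left out and 102 under the other settings, and 0 named genes changed direction with a call. Laminin over both fractions stayed at 0 throughout. PROM1 ranged from 0.174 to 0.328 and passed only without the untreated CD133- array of xenograft 1.

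The laminin effect in CD133+ cells was less stable. The count of 42 was 83 with only genes above the median mean, 122 with a mean-variance trend and robust prior, and 0 to 26 with 1 array left out. The interaction of 9 genes became 3 with averaged probe sets and 18 with the trend, and 0 to 0 with 1 array left out. Of 19 named calls for laminin in CD133+ cells, 0 held with every array left out and 6 under the other settings. The CD133 by xenograft interaction was 930 with the trend and 22 to 307 with 1 array left out. The xenograft count was 257 with genes above the median mean, 286 with the trend, 53 with every probe set on its own, and 2 to 73 with 1 array left out. Within CD133+ cells it was 6 and within CD133- cells 1617. CD133 without laminin gave 607 to 1681 genes and on laminin 103 to 1451 with 1 array left out. The cause was not tested for any of these, and a lone array left in a group is assumed to vary like the others.

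The block of arrays from 1 xenograft mattered where groups were small. With no replicate block CD133 gave 3228 genes, laminin 0, laminin within CD133+ cells 9, within CD133- cells 0, the interaction 5, CD133 without laminin 1428 and on laminin 757. With a replicate block of each xenograft and fraction, laminin within CD133+ cells gave 168 and the interaction 23. That alternative, the list tests within fractions, the split of the xenograft comparison by fraction and the fit without the CD133- arrays of xenograft 2 were chosen after seeing the data.

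Of the CD133 lists, 10 in place of 16 passed after cyclic loess normalization, and 12 to 16 with 1 array left out. For laminin 6 to 14 passed with 1 array left out, within CD133+ cells 8 to 15, within CD133- cells 0 to 8, for the interaction 7 to 13 and for CD133 by xenograft 6 to 10. Within CD133- cells 3 lists passed with genes above the median mean and 2 with a mean-variance trend. Cell cycle lists changed direction with single arrays. These genes differed between the xenografts mainly in CD133- cells. CDK1, for example, averaged 9.95 and 11.03 in CD133- cells of xenografts 1 and 2, beside 11.29 and 11.41 in CD133+ cells. The fit has 1 xenograft term for both fractions, so leaving out 1 array can let that difference into the laminin contrast. The changes of direction are therefore no evidence about laminin, and their cause was not tested. The adjusted p of S phase genes for laminin in CD133+ cells ran from 1.08e-06 to 0.98, changing direction without the untreated array of xenograft 1 (0.867) or the laminin array of xenograft 2 (0.98). That of G2 and M phase genes ran from 5.09e-06 to 0.336, changing direction without the same arrays (0.00799 and 0.0207). In CD133- cells S phase genes ran from 2.7e-08 to 0.826, changing direction without the laminin array of xenograft 1 (0.826) or the untreated array of xenograft 2 (0.546), and G2 and M phase genes from 3.87e-08 to 0.174, changing direction without the latter (0.00125). For the interaction G2 and M phase genes ran from 0.000308 to 0.0161, changing direction without the laminin arrays of xenograft 1 (CD133+ 0.00266, CD133- 0.0126) or the untreated arrays of xenograft 2 (CD133+ 0.0161, CD133- 0.00203). Signal near the floor limits dim genes such as PROM1.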

Other observations

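In CD133+ cells on laminin the endothelial marker gene KDR, which encodes a VEGF receptor, averaged 6.67, beside 4.73 without laminin and 8.74 in CD133- cells of each xenograft. ITGA3, the alpha chain of a laminin-binding integrin, averaged 5.52 without laminin and 7.40 on laminin in CD133+ cells, and 8.58 and 8.54 in CD133- cells of xenografts 1 and 2. THBS1 averaged 3.39 and 6.33 in CD133+ cells, and 8.08 and 6.89 in CD133- cells of xenografts 1 and 2.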
